A study of Mus musculus with 9 samples.

How the data were processed

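Small RNA sequencing was analysed from extracellular vesicles released by a conditionally immortalized mouse podocyte line. Podocytes are the epithelial cells that wrap the capillaries of the kidney filter, and such a line divides at a permissive temperature and differentiates after a shift to body temperature. Per the labels' protocols, cells were differentiated for 10 days in medium with fetal bovine serum and then kept for 48 h in 1 of 3 media. These were normal glucose (5.3 mM), high glucose (30 mM), and 5.3 mM glucose with 24.7 mM mannitol, a sugar alcohol used as the control for osmolality. Vesicles were precipitated from the culture supernatant with a polymer reagent, and adapter-ligated small RNA libraries were size selected on a gel, per the labels' protocols. Polymer precipitation collects vesicles together with other RNA carriers of the medium, and the labels do not say whether the serum had been depleted of its own vesicles.

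Each of the 9 libraries had a table of 1915 mouse miRNA identifiers with 2 value columns. Per the file headers, the first holds total counts, and these whole-number counts per miRNA were used as deposited. Per the file headers, the second holds normalized values, which were RPM values equal to the count divided by a single constant per library. That constant was many times larger than the sum of the miRNA counts, and what it counts is not given in the sources used here. Per the submitters' processing notes, bcl2fastq, BWA and the mouse build mm10 were used; their versions and settings are not given in the sources used here. No count from 1 to 9 occurred in any library, so a listed 0 stands for 0 to 9 reads, and levels and fold changes of rare miRNAs carry that limit. Several related identifiers had identical counts in all libraries, such as miR-486a-5p and miR-486b-5p or miR-199a-3p and miR-199b-3p. Their reads cannot be assigned to a copy, and values of such near-identical family members are uncertain.

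Groups were taken from the treatment label of each sample, 3 libraries per group, and the labels give no batch. The first title of each group has no number and was taken as replicate 1. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Counts of libraries within a group were compared by a chi-square statistic, which covers counting error only and serves only to find a library deposited more than once. Its value per degree of freedom was 95.4 to 838 over the 9 such pairs, so none was found. Each library was counted as 1 replicate because the labels list it as a separate sample.

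Levels are given as CPM relative to all miRNA counts of the library, mean ± SD over the 3 libraries of a group. Fold changes came from edgeR 4.0.16 in R 4.3.3, with TMM scaling, expression filtering by group and the robust quasi-likelihood test. All 9 libraries entered a joint fit, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was 0.05. Of 479 miRNAs listed in any library, 361 passed the filter and 260 were listed in all 9 libraries. SE and 95% intervals of log2 fold changes came from the same fit. Adjusted p-values of miRNAs are from edgeR unless another tool is named. Unadjusted p-values of single miRNAs are from the same edgeR fit and are given only to describe them.

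The lists of miRNAs and the rule for naming miRNAs were fixed before the data were examined, as were the tests and most alternatives. The lists were the miR-30, let-7 and miR-200 families, the miR-17 cluster with its paralogs, and the miR-34 and miR-15/16 families. Others held miRNAs linked to diabetic kidney disease, mesenchymal, kidney tubule, endothelial, striated muscle and neural, and blood, immune and liver miRNAs. The last were the imprinted Dlk1-Dio3 locus, the Sfmbt2 intron cluster, and identifiers attributed to rRNA or tRNA fragments. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between miRNAs. Identifiers with identical counts stayed separate members in list counts, medians and tests. These were miR-486a-5p and miR-486b-5p among blood, immune and liver miRNAs, and miR-199a-3p and miR-199b-3p among mesenchymal miRNAs. In the Sfmbt2 cluster they were miR-669a-3p and miR-669o-3p. Adjusted p-values of lists were computed by the Benjamini-Hochberg method over all lists and comparisons. Named miRNAs were those past the threshold, and where fewer than 5 passed, the 5 higher and 5 lower with the smallest unadjusted p, as values that did not pass. From each list the members past the threshold were named, or otherwise the 2 with the highest mean CPM, and also the 10 most abundant miRNAs. Named outside this rule were the list members miR-30e-5p, miR-215-5p, miR-17-5p and miR-20a-5p, and also miR-669n. Those list members had the sign of the list result beside which they stand. Any other miRNA whose fold change is given outside this rule is said to be so.

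Library measures were compared between groups with two-sided exact permutation tests. With 3 libraries against 3 these cannot give a p below 0.1. Alternatives planned beforehand were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals, other filters, a replicate block, pairwise fits, a fold threshold, an estimated correlation for the lists, and leaving out each library. Chosen after seeing the data were a fit of miRNAs listed in all libraries, listed zeros set to 9 reads, scaling to the library constant, identical rows counted once, and removal of each library's GC trend. For that trend, GC content was taken from the side of the annotated hairpin that holds the miRNA arm, since mature sequences were not used here. For identifiers without a named arm it was taken from the whole hairpin. A value was found for 348 of the 361 tested miRNAs in GENCODE vM21 (GRCm38), which also gave the 1-based hairpin coordinates. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

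The fit was tested on counts simulated for all 9 libraries, with 479 miRNAs and 10 runs, and with changes added to the high glucose libraries. The shares below are for high glucose against normal glucose. With 20 changed miRNAs, 4.05% of those changed 2-fold, 62.5% of those changed 4-fold and 70.6% of those changed 8-fold were called. At a mean CPM of at least 100, all 4-fold and 8-fold changes were called. With 200 changed miRNAs these shares over all tested miRNAs were 31.0%, 68.1% and 72.5%, and false calls made up 9.76% of calls with 20 changed and 2.35% with 200 changed. At a mean CPM of at least 100, 98.2% of 4-fold changes were called with 200 changed. The simulation drew each miRNA independently and with the same dispersion in all groups. Its shares may therefore not hold in the real libraries and exclude no change there. Total miRNA counts were 725211 to 2553690 per library, and the median 95% interval reached 0.89 log2 units to either side in high glucose against normal glucose. It reached 0.65 for the 76 miRNAs with a mean CPM of at least 1000. The biological coefficient of variation was 53.2% by the common estimate.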

Results

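The series asked how high glucose alters the miRNAs that podocytes release in extracellular vesicles, with mannitol as the control for osmolality. Total miRNA counts were 1539514, 1087144 and 1107224 in the normal glucose libraries. They were 1329426, 1588723 and 2269776 with mannitol, and 725211, 1276674 and 2553690 in high glucose. The mean number of miRNAs at a CPM of at least 10 was 319 ± 13.5 in normal glucose, 314 ± 9.29 with mannitol and 296 ± 8.5 in high glucose (SD, n = 3 each). In high glucose replicate 1 the limit of 10 reads lay above 10 CPM, so that its number at that CPM, 296, was that of all miRNAs listed there. All fold changes below are log2 values from the joint edgeR fit, higher meaning higher in the first group named.

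Vesicle miRNA was dominated by a small set. By the mean over all 9 libraries the most abundant was miR-30a-5p, a member of a family expressed at high levels in podocytes, at 95933 ± 9828 CPM in normal glucose, 101177 ± 31290 with mannitol and 152745 ± 39064 in high glucose (SD, n = 3 each). Its hairpin lies on chromosome 1 at 23272269 to 23272339 on the plus strand, outside any annotated host gene of that strand. Next came miR-10a-5p (chromosome 11, 96317165 to 96317274) and miR-10b-5p (chromosome 2, 74726070 to 74726137, in introns of Hoxd3 and Hoxd4), which derive from Hox gene clusters. In normal glucose miR-10a-5p stood at 100346 ± 5650 CPM, above the mean of miR-30a-5p there, and miR-10b-5p at 94703 ± 6842 CPM. The growth-associated miR-21a-5p reached 53916 ± 3811 CPM there and 65154 ± 15994 CPM in high glucose. The remaining members of the top 10 were miR-378a-3p, miR-30d-5p, miR-27b-3p, miR-25-3p, miR-151-3p and miR-183-5p. The 10 most abundant miRNAs of each library together took 55.4% ± 0.527 of miRNA counts in normal glucose, 54.0% ± 3.89 with mannitol and 59.7% ± 3.18 in high glucose (SD, n = 3 each). The exact permutation p was 0.1 for high glucose against normal glucose, the smallest this design allows, and 0.2 for high glucose against mannitol. High glucose replicate 1, at 56.01%, lay barely above normal glucose replicate 3, at 55.95%. Of 57 exact permutation tests of library measures, 3 reached a p of 0.1. These were this share and the summed miR-30 level in high against normal glucose, and the summed tubule level in high glucose against mannitol (ratio 1.47). The smallest Benjamini-Hochberg adjusted exact p was 0.891.

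**Figure D1:**
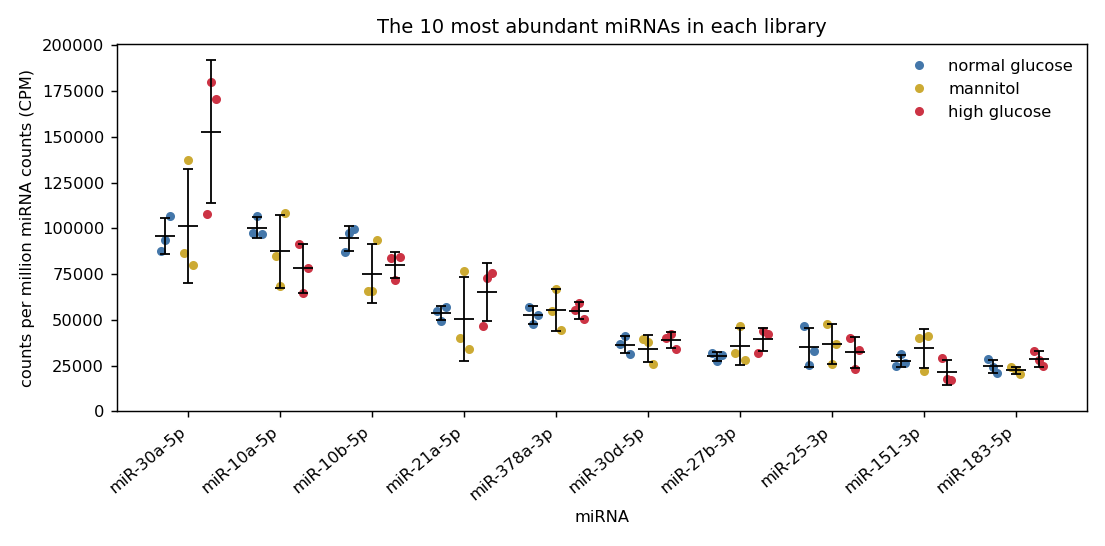
CPM relative to all miRNA counts (vertical axis) of the 10 most abundant miRNAs in each of the 9 libraries; points are libraries, coloured by group, and bars give the mean and SD of 3 libraries. For miR-30a-5p the high glucose mean is 152745 CPM against 95933 CPM in normal glucose and 101177 CPM with mannitol, and no miRNA passed the adjusted threshold in any comparison.

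High glucose was compared with normal glucose to find the miRNAs that differ with the treatment as a whole. With the smallest unadjusted p among the higher miRNAs, miR-30a-5p had a log2 fold change of 0.79 (SE 0.32, 95% interval 0.12 to 1.47) and was higher in all 9 pairs of libraries. The cartilage-associated miR-140-3p had 0.63 (SE 0.27), miR-3535 0.75 (SE 0.33), miR-101a-3p 0.87 (SE 0.42) and miR-101b-3p 0.76 (SE 0.38). Among lower values, miR-615-3p, encoded in a Hoxc5 intron on chromosome 15 at 103014910 to 103015001, had -1.06 (SE 0.40), at 2797 ± 1154 CPM in high glucose and 5840 ± 2733 CPM in normal glucose (SD, n = 3 each). From the imprinted Dlk1-Dio3 locus, miR-543-3p had -1.17 (SE 0.46) and miR-409-3p -0.85 (SE 0.34), while miR-151-5p had -1.35 (SE 0.60) and miR-1964-3p -0.96 (SE 0.44). None of these passed. Without normal glucose replicate 2, miR-615-3p had -0.49, miR-543-3p -0.54, miR-409-3p -0.44 and miR-1964-3p -0.26, while miR-151-5p had -0.78 without normal glucose replicate 3 and miR-101a-3p 0.57 without high glucose replicate 2. With edgeR, 0 of 361 miRNAs passed the adjusted threshold, 10 had an unadjusted p under 0.05, and the smallest adjusted p was 0.995. DESeq2 and limma-voom also called 0, with 15 and 5 miRNAs at an unadjusted p under 0.05. With a library left out, edgeR's count at that p was 1 (without high glucose replicate 2) to 25 (without mannitol replicate 2). The libraries of the groups did not overlap for 34 of 361 miRNAs, where chance gives 10%. Without the expression filter edgeR called miR-9-5p (2.37) and miR-6538 (-7.28). Of these, miR-9-5p stood at 254 CPM in high glucose replicate 1 and at most 96.3 CPM elsewhere, and miR-6538 was listed at 0 in 6 of the 9 libraries, all 3 high glucose libraries included, so that its fitted value is no measure of size. Both were named after their values were seen.

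In the same comparison the kidney tubule list was higher as a group, with 3 of 3 tested members higher and a median log2 fold change of 0.58. The adjusted p by camera was 0.0278 with the preset correlation, and the adjusted p was 0.593 by camera with an estimated correlation. Its members were miR-192-5p at 0.42 (SE 0.30), miR-194-5p at 0.63 (SE 0.32) and miR-215-5p at 0.58 (SE 0.42), and all 3 also belong to the diabetic kidney list. Summed over the tubule list, levels were 3993 ± 894 CPM in high glucose and 3082 ± 690 CPM in normal glucose (SD, n = 3 each), a ratio of 1.30 (exact permutation p = 0.3). High glucose replicate 2, at 3323 CPM, lay below normal glucose replicates 2 and 3. The call was lost in camera without normal glucose replicate 1 (adjusted p = 0.239), high glucose replicate 1 (adjusted p = 0.0890) or mannitol replicate 3 (adjusted p = 0.0635), and the adjusted p ranged from 0.0135 to 0.593 over the alternatives. No member passed over all miRNAs or when adjusted over the list alone, a count of 0 by edgeR in both cases, with 0 members at an unadjusted p under 0.05. The miR-30 family had 5 of 5 members higher (median 0.17, or 4 of 5 when scaled to the library constant), with miR-30e-5p at 0.73 (SE 0.50) and miR-30d-5p at 0.17 (SE 0.27), and did not pass in camera (adjusted p = 0.0763). It passed in camera without normal glucose replicate 2 (adjusted p = 0.0384), without mannitol replicate 2 (adjusted p = 0.0376) and with the numbers of the titles as a replicate block (adjusted p = 0.0362), and its adjusted p reached up to 0.593 with an estimated correlation. Summed over the family, levels were 193899 ± 39136 CPM in high glucose and 134348 ± 7123 CPM in normal glucose (SD, n = 3 each), a ratio of 1.44. That difference reached the smallest exact permutation p, 0.1. Most of it came from miR-30a-5p, whose means are given above, so it says little about the family as a whole. Fold changes across the 251 miRNAs with a GC value that were listed in all libraries ran against GC content (Spearman's rho -0.261 across miRNAs, which are not independent replicates). Beside the tubule list, and without passing, the median was -0.29 for blood, immune and liver miRNAs (5 of 7 lower), -0.18 for muscle and neural miRNAs (6 of 9 lower) and 0.11 for mesenchymal miRNAs (6 of 8 higher).

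High glucose was compared with mannitol to ask for differences at matched osmolality. The smallest unadjusted p belonged to miR-3535, with a log2 fold change of 1.09 (SE 0.34), at 186 ± 18.6 CPM in high glucose and 96.4 ± 29.8 CPM with mannitol (SD, n = 3 each). A member of the growth-promoting miR-17 cluster, miR-19b-3p, had 1.58 (SE 0.52, 95% interval 0.47 to 2.69), and its reads can come from chromosome 14 at 115044305 to 115044391 or chromosome X at 52741983 to 52742066. Further higher values were 0.83 (SE 0.33) for miR-16-5p, 0.75 (SE 0.32) for miR-30a-5p and 0.61 (SE 0.24) for miR-182-5p. Lower values were -1.03 (SE 0.36) for miR-23b-5p, -1.01 (SE 0.35) for miR-7666-3p, -0.85 (SE 0.35) for miR-423-5p and -0.88 (SE 0.36) for the erythroid miR-486a-5p and miR-486b-5p, whose counts are identical. None of these passed. Scaled to the library constant, values were 0.03 for miR-182-5p, 0.31 for miR-30a-5p, 0.37 for miR-16-5p and 0.59 for miR-3535, and -1.68 for miR-23b-5p, -1.71 for miR-7666-3p, -1.51 for miR-423-5p and -1.53 for miR-486a-5p. Without mannitol replicate 2, miR-30a-5p had 1.16, and without mannitol replicate 3, miR-423-5p had -0.40 and miR-486a-5p -0.53. With listed zeros set to 9 reads miR-182-5p had 0.40, and with the GC trend removed miR-7666-3p, whose side of the hairpin has 77.8% GC, had -0.50 (SE 0.35). With edgeR, 0 miRNAs passed, 19 had an unadjusted p under 0.05 and the smallest adjusted p was 0.704, while DESeq2 and limma-voom called 0, with 25 and 29 at an unadjusted p under 0.05. With a library left out, edgeR's 19 became 6 (without mannitol replicate 3) to 96 (without mannitol replicate 2). Without the expression filter edgeR called 3, miR-19b-3p (1.58, adjusted p = 0.0421), miR-1a-3p (-2.78) and miR-6538 (-9.67), and without mannitol replicate 2 it called miR-19b-3p alone (2.47, adjusted p = 0.0465). Over the alternatives run, the adjusted p of miR-19b-3p ranged from 0.0421 to 0.9998 across edgeR, DESeq2 and limma-voom. Libraries of the groups did not overlap for 37 of 361 miRNAs, against 10% by chance.

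Of the lists fixed beforehand, 3 were higher in high glucose than with mannitol by camera with the preset correlation. With an estimated correlation all 3 calls were lost (adjusted p = 0.593 by camera for each). The miR-30 family had 5 of 5 members higher (median 0.41, adjusted p by camera = 0.0287), with miR-30a-5p at 0.75 (SE 0.32) and miR-30d-5p at 0.34 (SE 0.27). The miR-17 cluster list had 6 of 8 higher (median 0.52, adjusted p by camera = 0.0191), with miR-20a-5p at 0.70 (SE 0.42) and miR-17-5p at 0.55 (SE 0.34), but its most abundant members miR-25-3p and miR-92a-3p had -0.03 (SE 0.27) and -0.61 (SE 0.40). Summed over that list, levels were 43246 ± 10708 CPM in high glucose and 51462 ± 15230 CPM with mannitol (SD, n = 3 each), a ratio of 0.840 (exact permutation p = 0.4). In high glucose against normal glucose the miR-17 list had a median of 0.17 and did not pass in camera. Its call against mannitol and its call in mannitol against normal glucose, given below, rest on the same mannitol libraries. The summed miR-30 level of mannitol replicate 2, 177083 CPM, lay above the 149949 CPM of high glucose replicate 1, while between libraries of the same number in the titles high glucose was higher in 3 of 3 (exact permutation p = 0.25, the smallest that 3 such differences allow). Between the group means most of the summed miR-30 difference again came from miR-30a-5p. The diabetic kidney list had 13 of 17 higher (median 0.33, adjusted p by camera = 0.0191), with miR-21a-5p at 0.51 (SE 0.35) and miR-192-5p at 0.69 (SE 0.30), and 8 of its tested members belong to other lists, as do 2 of the miR-17 list. No member passed over all miRNAs or when adjusted over the list alone, and each list had 1 member at an unadjusted p under 0.05 in edgeR. All 3 calls were also lost in camera without mannitol replicate 3, with adjusted p = 0.120, 0.0635 and 0.116 in the order above, and the miR-30 call without high glucose replicate 2 (adjusted p = 0.0631) or with the GC trend removed (adjusted p = 0.0865). In that last setting the miR-30 median was 0.28 with 4 of 5 higher, and miR-30a-5p had 0.75 (SE 0.31). Over the alternatives of camera the adjusted p reached down to 0.0146, 0.000756 and 0.00915, and up to 0.593 for each. Scaled to the library constant, the median of all tested miRNAs moved to -0.59, and the list medians became -0.17 for miR-30, 0.08 for miR-17 and -0.11 for diabetic kidney. Relative to all tested miRNAs they stayed higher, by 0.42, 0.67 and 0.48. Fold changes ran against GC content here too (Spearman's rho -0.414 across 251 miRNAs). Beside these lists, markers of other cells went both ways without passing. Their counts and medians keep identifiers with identical counts as separate members. The median was -0.57 for blood, immune and liver miRNAs (5 of 7 lower), -0.56 for muscle and neural miRNAs (7 of 9 lower), 0.51 for mesenchymal miRNAs (7 of 8 higher, or -0.10 with 3 of 8 higher when scaled to the library constant) and 0.49 for tubule miRNAs (3 of 3 higher, or 2 of 3 so scaled). In the untested endothelial list miR-126a-3p had 0.52 (SE 0.40) and miR-126a-5p 1.59 (SE 1.85), with 1 of 2 higher when scaled to the library constant, and miR-2137, attributed to rRNA or tRNA fragments, had -0.91 (SE 0.48).

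**Figure D2:**
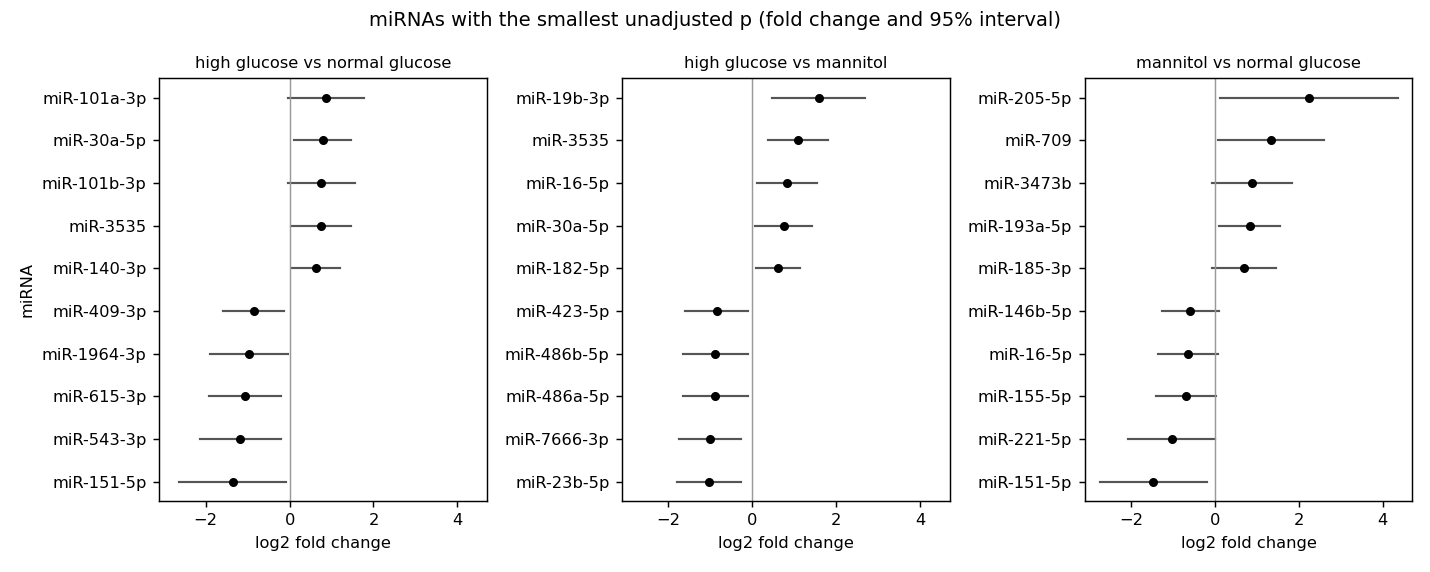
Log2 fold changes (horizontal axis, points) with 95% intervals (lines) of the 5 higher and 5 lower miRNAs with the smallest unadjusted p in each of the 3 comparisons, from the joint fit of 9 libraries. Intervals are not adjusted for the 361 miRNAs tested, and none of the miRNAs shown passed the adjusted threshold.

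Mannitol was compared with normal glucose to measure what added osmolality does without added glucose. Higher values were 0.82 (SE 0.34) for miR-193a-5p, 1.33 (SE 0.59) for miR-709, 0.88 (SE 0.45) for miR-3473b, 0.69 (SE 0.36) for miR-185-3p and 2.23 (SE 0.99) for the epithelial miR-205-5p. The last rested on mannitol replicate 1, at 129.4 CPM against at most 24.2 CPM in the other libraries, and without that replicate miR-205-5p had 0.80, miR-709 0.66 and miR-3473b 0.57. Lower values were -1.48 (SE 0.60) for miR-151-5p, -1.04 (SE 0.48) for miR-221-5p, -0.69 (SE 0.34) for the immune-associated miR-155-5p, -0.64 (SE 0.33) for miR-16-5p and -0.59 (SE 0.32) for miR-146b-5p. None of these passed. Scaled to the library constant, values were 1.33 for miR-193a-5p, 1.16 for miR-185-3p, -0.98 for miR-151-5p, -0.51 for miR-221-5p, -0.17 for miR-155-5p, -0.27 for miR-16-5p and -0.11 for miR-146b-5p. Without normal glucose replicate 3 they were -0.84 for miR-151-5p, -0.63 for miR-221-5p, -0.33 for miR-155-5p and -0.42 for miR-16-5p. With edgeR 0 miRNAs passed and 5 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, with 3 each at an unadjusted p under 0.05. With a library left out, edgeR's 5 became 1 (without mannitol replicate 1) to 36 (without mannitol replicate 2). Libraries of both groups did not overlap for 12 of 361 miRNAs, against 10% by chance. Without the expression filter edgeR called miR-1a-3p (2.08), which stood at 3822 CPM in mannitol replicate 3 and at most 917 CPM elsewhere. With listed zeros set to 9 reads it called miR-669n (-2.14), which was listed in normal glucose replicate 1 alone, at 83 counts. By camera with the preset correlation the miR-17 list was lower with mannitol (adjusted p = 0.0191), but not with an estimated correlation (adjusted p = 0.593). It had 7 of 8 members lower and a median of -0.27, among them miR-20a-5p at -0.50 (SE 0.42) and miR-19b-3p at -0.78 (SE 0.52), but its most abundant members miR-25-3p and miR-92a-3p had 0.00 (SE 0.27) and -0.08 (SE 0.40). Summed levels were 51462 ± 15230 CPM with mannitol and 50064 ± 13710 CPM in normal glucose (SD, n = 3 each), a ratio of 1.03 (exact permutation p = 1). The call was lost in camera without mannitol replicate 3 (adjusted p = 0.166) or normal glucose replicate 1 (adjusted p = 0.119), and its adjusted p ranged from 0.0034 to 0.593 over the alternatives. No member passed over all miRNAs or when adjusted over the list alone by edgeR, and 0 had an unadjusted p under 0.05. Scaled to the library constant, the median of all tested miRNAs was 0.50 and that of the list 0.10, which stayed lower than all tested miRNAs (-0.41). The miR-17 calls of this comparison and of high glucose against mannitol share the mannitol libraries and are not separate results. The let-7 family, linked to differentiation, had 9 of 9 members lower (median -0.24, or 0.35 with 2 of 9 lower when scaled to the library constant) and did not pass in camera (adjusted p = 0.0860), except without normal glucose replicate 1 (adjusted p = 0.0215), normal glucose replicate 3 (adjusted p = 0.0309) or mannitol replicate 2 (adjusted p = 0.0407), or with the replicate block (adjusted p = 0.0467). Beside the miR-17 list, muscle and neural markers had a median of 0.55 (7 of 9 higher) and tubule markers 0.10, miR-126a-3p had -0.58 (SE 0.40), miR-126a-5p -1.47 (SE 1.84) and miR-2137 0.79 (SE 0.48), and no such list passed. Fold changes ran with GC content in this comparison (Spearman's rho 0.252 across 251 miRNAs).

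In the joint fit with TMM scaling the remaining lists did not pass in any comparison, and the following adjusted p-values are from camera. The miR-34 and miR-15/16 families, linked to p53 and apoptosis, had adjusted p = 0.384 in high glucose against normal glucose, 0.0639 against mannitol (5 of 5 higher, or 3 of 5 when scaled to the library constant) and 0.0790 in mannitol against normal glucose. They passed against mannitol with library totals (adjusted p = 0.0473) or without normal glucose replicate 2 (0.0426), mannitol replicate 2 (0.0376) or high glucose replicate 1 (0.0439), and in mannitol against normal glucose without normal glucose replicate 2 (0.0218) or mannitol replicate 2 (0.0310). Their most abundant member miR-34c-5p stood at 2404 ± 762 CPM in high glucose and 1658 ± 72.4 CPM in normal glucose (SD, n = 3 each). Summed over the list, levels were 2818 ± 828 CPM in high glucose and 2194 ± 1428 CPM with mannitol (SD, n = 3 each, exact permutation p = 0.6). Mannitol replicate 2 had the highest sum, 3841 CPM. In the same order, the epithelial miR-200 family had adjusted p = 0.423, 0.262 and 0.367, and miR-200b-3p had fold changes of 0.31 (SE 0.27), 0.39 (SE 0.27) and -0.08 (SE 0.27). The mesenchymal list had adjusted p = 0.367, 0.555 and 0.897, and miR-143-3p had -0.04 (SE 0.42), 0.32 (SE 0.42) and -0.36 (SE 0.42). Markers of blood, immune cells and liver, which serum also carries, had adjusted p = 0.193, 0.173 and 0.633. The liver miRNA miR-122-5p stood at 17097 ± 6636 CPM in normal glucose, 17046 ± 5427 with mannitol and 13668 ± 6430 in high glucose (SD, n = 3 each). Striated muscle and neural markers had adjusted p = 0.673, 0.202 and 0.262, with miR-206-3p at -0.50 (SE 0.30), -0.05 (SE 0.30) and -0.45 (SE 0.30). The Dlk1-Dio3 list had adjusted p = 0.260, 0.262 and 0.753, and its most abundant member miR-127-3p had 0.14 (SE 0.32), -0.34 (SE 0.32) and 0.48 (SE 0.32). The Sfmbt2 cluster had adjusted p = 0.897, 0.687 and 0.729, with miR-669c-5p at -0.40 (SE 0.36), 0.03 (SE 0.36) and -0.43 (SE 0.36).

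Among lists already named, the miR-17 list had adjusted p = 0.360 by camera in high glucose against normal glucose, and the diabetic kidney list 0.132 there and 0.0830 in mannitol against normal glucose. The tubule list had adjusted p = 0.0755 by camera against mannitol and 0.897 in mannitol against normal glucose, the miR-30 family 0.285 in the latter, and let-7 0.346 and 0.687 in the high glucose comparisons. Lists that passed in camera only with a library left out were, in high against normal glucose without normal glucose replicate 1, blood, immune and liver (adjusted p = 0.0427), Dlk1-Dio3 (0.0485) and let-7 (0.0409, or 0.0411 without high glucose replicate 2). The tubule list did so against mannitol without high glucose replicate 2 (adjusted p = 0.0492), and the diabetic kidney list in mannitol against normal glucose without mannitol replicate 2 (0.0179). The endothelial list had only miR-126a-3p and miR-126a-5p tested, and the list of rRNA or tRNA fragments only miR-2137. Both lists were too short for camera. Levels of miR-126a-3p were 467.3 ± 292, 317 ± 18.8 and 426 ± 199.3 CPM in normal glucose, mannitol and high glucose, and those of miR-2137 were 420 ± 185, 778 ± 540.7 and 372 ± 269 CPM (SD, n = 3 each). Median, mean and test differed in sign for some lists. In high glucose against normal glucose, miR-200 had a median of 0.23 and a mean of -0.06, the muscle and neural list tested lower with a mean of 0.06, and the Sfmbt2 cluster tested higher with a median of -0.31. In mannitol against normal glucose, the mesenchymal and the blood, immune and liver lists tested higher with medians of -0.11 and -0.05. There the tubule list tested lower with a median of 0.10, and the Dlk1-Dio3 list tested higher with a mean of -0.005.

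Both comparisons of high glucose share its libraries. With edgeR, 0 miRNAs passed in both, and DESeq2 and limma-voom also gave 0. At an unadjusted p under 0.05 in both and the same direction there were 5, namely miR-30a-5p, miR-3535, miR-615-3p, miR-543-3p and, named after its values were seen, miR-433-3p of the Dlk1-Dio3 locus, with -0.88 (SE 0.41) and -0.89 (SE 0.41). Simulated unchanged libraries gave a mean of 3.38 (95% between 0.475 and 7), and independent lists would give 0.280. The count of 5 became 22 without mannitol replicate 2 and 1 without mannitol replicate 1, mannitol replicate 3 or high glucose replicate 2. It became 12 with the numbers of the titles as a replicate block, a design for which no simulation was run. Fold changes of high glucose and of mannitol against the shared normal glucose libraries had a Pearson correlation of 0.396 across miRNAs, which are not independent replicates. Simulation with no effect gave 0.574, with 95% of values between 0.308 and 0.758. The covariance was 0.233 against 1.24 in the simulation (95% of values between 0.399 and 1.88). At a mean CPM of at least 100 the correlation was 0.0878 and the covariance 0.0112, against 0.513 (95% between 0.383 and 0.626) and 0.0812 (95% between 0.0538 and 0.116) in the simulation. Both covariances and the latter correlation lay below the simulated range. However, the simulation drew each miRNA independently and with the same dispersion in all groups. In the libraries a single axis, described below, held 47.6% of the variance. The simulated ranges thus cannot show whether the count, the correlations or the covariances exceed what sharing gives. Over all tested miRNAs the covariance was 1.46 with DESeq2. With a library left out it was 0.0162 (without mannitol replicate 2) to 2.06 (without normal glucose replicate 1). The 3 control libraries cannot be split into parts of at least 2. Over all groups together edgeR called 0 miRNAs, with 7 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0, with 12 and 7.

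Libraries of a group differed along an axis that cut across the groups. Over the 260 miRNAs listed in all libraries, the leading principal axis held 47.6% of the variance, and 29.9% of the variance of its scores lay between groups (exact permutation p = 0.336 over 280 groupings). High scores belonged to mannitol replicates 1 and 3, and low scores to mannitol replicate 2 and high glucose replicates 2 and 3. Among libraries of the same number in the titles, the high glucose score and GC slope were the lowest in 3 of 3 sets. For the GC slope, the log2 level of each miRNA was taken as its deviation from its mean over the 9 libraries. The sign of a slope is thus relative to the other libraries and does not tell how levels themselves relate to GC content. This slope was 0.007 ± 0.147 log2 units per 10 percentage points in normal glucose, 0.10 ± 0.22 with mannitol and -0.11 ± 0.16 in high glucose (SD, n = 3 each). All 4 libraries with a positive score had a positive GC slope, and all 5 with a negative score a negative slope. Score and slope were computed from the same levels, so this match is not separate from the relation of loadings to GC content given below.

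**Figure D3:**
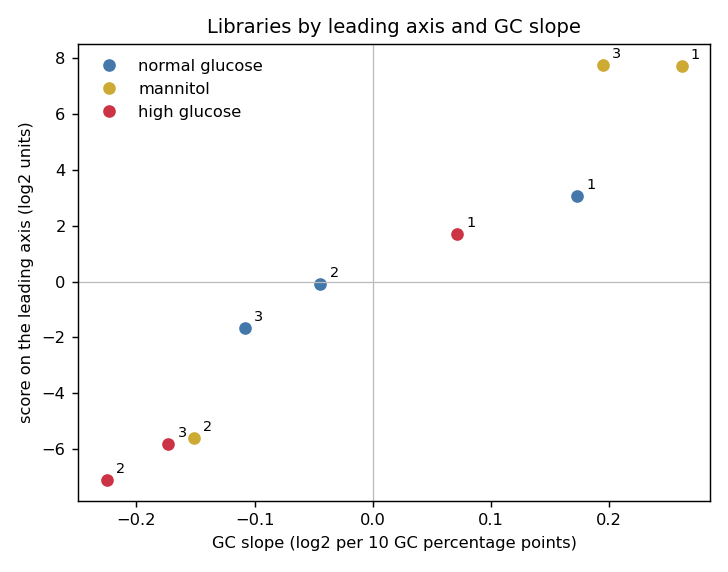
Score of each of the 9 libraries on the leading principal axis (vertical, log2 units) against its GC slope (horizontal, log2 units per 10 percentage points), coloured by group and numbered by replicate. The slope is that of the deviations of miRNA levels from their means over the 9 libraries, so its sign is relative to the other libraries. Mannitol replicates 1 and 3 lie at the top right and mannitol replicate 2 at the bottom left beside high glucose replicates 2 and 3. Score and slope were computed from the same levels and are not independent.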

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

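Chosen only after results were seen were the settings with miRNAs listed in all libraries, listed zeros at 9 reads, scaling to the library constant, identical rows counted once and GC trends removed. The count of 0 changed miRNAs by edgeR (10, 19 and 5 at an unadjusted p under 0.05 in high glucose against normal glucose, high glucose against mannitol, and mannitol against normal glucose) was also 0 by DESeq2 and limma-voom. Without a filter it was 2, 3 and 1, with 3 over any group and 1 in both high glucose comparisons. At an unadjusted p under 0.05 and 2-fold it was 4, 7 and 4. With listed zeros at 9 reads, mannitol against normal glucose and any group gave 1 each. Leaving out a library gave 0 to 1 in high glucose against mannitol and 0 elsewhere. The correlation of 0.396 was 0.256 with CPM of at least 10, 0.135 over miRNAs listed in all libraries, 0.129 with zeros at 9 reads, 0.239 with pairwise fits, 0.0878 at a mean CPM of at least 100, and 0.0112 (without mannitol replicate 2) to 0.770 (without normal glucose replicate 1) with a library left out. Of the 5 list calls, both of the miR-17 list share the mannitol libraries. The 5 calls became 0 with an estimated correlation, and 0 to 10 with a library left out (0 without mannitol replicate 3, 10 without mannitol replicate 2, 8 without normal glucose replicate 2). The cause of these shifts was not tested. Of list tests under single settings, 19 became calls, 15 lost theirs and the others kept their side. Fold changes of named miRNAs stayed within their error in 3375 cases, moved in 166 and passed the threshold in 2. Of 162, scaling to the constant turned the sign of 42. Of library measures 343 stayed and 5 moved. As a replicate block, the numbers of the titles gave 0 miRNAs in each comparison by edgeR, with 19, 52 and 17 at an unadjusted p under 0.05. The block kept all 5 list calls and added miR-30 in high glucose against normal glucose (adjusted p = 0.0362 by camera) and let-7 in mannitol against normal glucose (adjusted p = 0.0467). With the block 12 miRNAs had an unadjusted p under 0.05 in both high glucose comparisons and the same direction, against 5. Deviations of same-numbered libraries correlated above 0.1 in 7 of 9 pairs, at 0.197, 0.316 and 0.244 for high and normal glucose, 0.454, 0.521 and 0.169 for high glucose and mannitol, but 0.229, 0.0834 and -0.0583 for mannitol and normal glucose. The main fit, the permutation tests of 3 against 3 and the splits did not take the numbers as pairs, since the labels do not say what they mark. Yet all 9 libraries correlated best with their own number, which is known from the data alone. Grouped by number instead of treatment, the libraries gave 59 miRNAs at an unadjusted p under 0.05 over any group by edgeR, against 7. Other groupings gave up to 104. Depth limits rare miRNAs most, since a listed 0 hides up to 9 reads.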

Other observations

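The depth test of the leading axis and the serum percentile with identical miRNAs counted once were chosen after results were seen, as were the differences between libraries of the same number, and so were the miRNAs of the next paragraph and the alternatives with GC trends removed, listed zeros at 9 reads or scaling to the library constant.

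The muscle miRNA miR-1a-3p stood at 3822 CPM (8676 counts) in mannitol replicate 3 and at 917 CPM in normal glucose replicate 3, against 55.9 to 302 CPM in the other 7 libraries. Its fold change in high glucose against mannitol was -2.70 (SE 1.58) and did not pass by edgeR (adjusted p = 0.712). From the Hox clusters, miR-615-3p had -1.06 (SE 0.40) in high glucose against normal glucose, miR-10a-5p -0.29 (SE 0.25), miR-10b-5p -0.16 (SE 0.25), miR-196a-5p -0.02 (SE 0.28) and miR-196b-5p 0.10 (SE 0.35). The arms of the Mir30a hairpin were apart, with miR-30a-5p at 0.79 (SE 0.32) and miR-30a-3p at 0.15 (SE 0.26), a difference that was not tested. The sensory-organ cluster on chromosome 6 had 0.61 (SE 0.24) for miR-182-5p, 0.49 (SE 0.25) for miR-183-5p and 0.71 (SE 0.48) for miR-96-5p in high glucose against mannitol. From the Mir151 hairpin in a Ptk2 intron (chromosome 15, 73254815 to 73254882), miR-151-3p had a mean of 27842 CPM and miR-151-5p of 24.1 CPM. No biological explanation was tested for these values.

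The leading axis of variation cut across the groups, with both mannitol replicates 1 and 3 far from mannitol replicate 2. Library depth was left open by too few libraries, since scores and log2 totals, both centred within groups, gave a Spearman's rho of -0.267 (exact permutation p = 0.583; -0.333 to 0.286 with a library left out) and a Pearson's r of -0.212 (exact permutation p = 0.620), or 0.320 without the 2 libraries farthest from the median depth. A candidate explanation is a GC-dependent step of library making or sequencing, since loadings followed GC content as taken from the hairpins (Spearman's rho 0.433 across 251 miRNAs, bootstrap interval 0.320 to 0.533). The bootstrap resampled miRNAs, which are not independent replicates, and kept the axis of these 9 libraries, so its interval leaves out the spread between libraries. Carry-over from serum could not be decided, since the absolute median loading of its 4 members, all of the same sign, lay at percentile 93.5 of random lists, or 68.3 with the identical miR-486a-5p and miR-486b-5p counted once, and its most abundant member miR-122-5p (15937 CPM) had the smallest loading of them. RNA quality was not tested as a source of the axis. Its only tested marker, miR-2137, attributed to rRNA or tRNA fragments, is among the miRNAs that define the axis, with a loading of 0.108. It stood at 552 to 1395 CPM in the libraries with a positive score and at 166 to 415 CPM in those with a negative score. Differences between cultures stay open, untested.

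Large fold changes gathered in miRNAs listed at 0 in some libraries, where 32.0% of 101 had an absolute log2 fold change of at least 1 against 2.56% of those listed in all 9 libraries, averaged over the comparisons. The limit of 10 reads applied before deposit may account for this, since abundant miRNAs thinned to the same counts and held to that limit reached 33.0% ± 2.44 (SD, 100 draws). That is 1.03 times the observed share. Thinning without the limit gave 7.99% ± 1.67. A biological difference in rare miRNAs was not tested and stays open.

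Fold changes in both high glucose comparisons followed GC content, as did those of mannitol against normal glucose with the opposite sign (Spearman's rho 0.252 across miRNAs). A GC-dependent step that differs between single libraries and an effect of glucose on which miRNAs leave in vesicles, the latter untested, cannot be told apart as the source of that trend. The widest range of GC slopes inside a group, 0.41 with mannitol, was 1.96 times the difference between the high glucose and mannitol means and 3.57 times that between high and normal glucose. The slopes gave an exact permutation p of 0.4 for high against normal glucose and 0.2 for high glucose against mannitol, yet between libraries of the same number the high glucose slope was lower in 3 of 3 in each comparison (exact permutation p = 0.25, the smallest that 3 differences allow). With the trend removed the correlation ended by construction, while miR-30a-5p kept 0.79 (SE 0.31) and miR-615-3p -0.97 (SE 0.35) in high against normal glucose, neither past the adjusted threshold, and miR-7666-3p went from -1.01 (SE 0.35) to -0.50 (SE 0.35) in high glucose against mannitol.

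For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In high against normal glucose the real count by edgeR was 0 with at most 0 in another split (10 of 10 as large), 10 at an unadjusted p under 0.05 with at most 30 (6 as large), and 3 lists at an unadjusted p under 0.05 with at most 4 (4 as large). In high glucose against mannitol these were 0 with at most 68 (10 as large), 19 with at most 6.63 times as many (3 as large) and 5 lists with at most 5 (3 as large). In mannitol against normal glucose they were 0 with at most 0 (10 as large), 5 with at most 71 (9 as large) and 4 lists with at most 7 (4 as large). The split with 68 calls put mannitol replicates 1 and 3 with high glucose replicate 1, and that with 71 put them with normal glucose replicate 1, which points to a structure of the samples along the leading axis. Over any group chance was not excluded for the 7 miRNAs at an unadjusted p under 0.05, with at most 104 in another of 100 splits (65 as large). The adjusted count there was 0 with at most 33 in another split (100 as large), and since every split is as large as a count of 0, such counts by edgeR test nothing about chance, here or in the 3 comparisons above.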
